A study of Mus musculus with 8 samples.

How the data were processed

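RNA was sequenced from the bone marrow of C57BL/6 mice that had died of a transplanted leukemia, 8 libraries in 3 groups. The marrow carried the fusion gene AML1-ETO with Meis2 (AE+Meis2, n = 3), the truncated splice form AML1-ETO9a with Meis2 (AE9a+Meis2, n = 3) or AML1-ETO9a alone (AE9a, n = 2). Groups and replicate numbers came from the sample titles. The labels do not say which donor animal, transduction or sequencing batch a library belongs to, so p-values measure the spread between these libraries, part of which may be technical.

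The authors deposited 1 table of FPKM (fragments scaled by transcript length and by the mapped fragments of the library) for 23997 genes in the 8 libraries. Per the submitters' processing notes, TopHat, Cufflinks and Cuffdiff were used with the mouse build mm10; their versions and settings, the annotation and the normalization between libraries are not given in the sources used here. FPKM divides by transcript length and depth, so very short transcripts take large and unsteady values: 1239 small RNA entries (microRNA and small nucleolar RNA genes among them) held between 8.68% and 38.0% of a library's summed FPKM. Several abundant genes are listed at exactly 0 in every library of 1 group, which can be a failed estimate. For these genes the value of each library is given, with no mean and no fold change.

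The table holds no read counts. Where whole fragments are counted, the low values of a gene are multiples of what 1 fragment is worth, so the most common log2 ratio of low values (9343 genes with FPKM up to 1) between libraries estimates their relative depth. On this measure AE9a+Meis2 replicate 2 was the deepest and AE9a replicate 1 the shallowest, an 8.28-fold range. The estimate is rough: the most common ratio held between 3.99% and 14.2% of the genes compared, and 78.6% of 336 triangles of libraries closed within a log2 tolerance of 0.05. Absolute depth is unknown, and no counting interval is given.

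All values were taken to log2(FPKM + 1), so fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Genes with an FPKM of at least 1 in at least 2 libraries were tested, 12565 in all. limma 3.58.1 in R 4.3.3 fitted 1 coefficient per group over all 8 libraries, with empirical Bayes moderation along the intensity trend (2.29 prior and 5 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and ± gives the standard error of a log2 difference. Cuffdiff needs alignments and could not be run on FPKM. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

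Gene lists for signalling, metabolism, blood lineages, other cells of the marrow, RNA quality and donor sex, 40 in all, were fixed before the data were examined, as were the design, the threshold, the rule for named genes and the first set of other settings. Of these, 39 had at least 3 tested members and were tested with camera in limma at a preset correlation between genes of 0.01. P-values were adjusted by the Benjamini-Hochberg method over the lists of a comparison. For some lists the text says which or how many members passed limma adjusted over the list alone. A member named without such a statement need not have passed. A list score is the mean log2(FPKM + 1) of the tested members. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were alternatives. Camera compares a list with the other genes, while fry does not.

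The genes named in the text follow a rule fixed with the lists. Meis2, Runx1 and Runx1t1 come first, in every library. In each comparison come up to 10 genes with the largest rise and up to 10 with the largest fall among those past the threshold, with no overlap between the libraries of both groups and a mean of at least 5 FPKM in the higher group. Predicted genes, small RNAs and antigen receptor segments are left out of this part. Where fewer than 10 passed in a direction, up to 5 more were named by smallest p as not passing. Each list contributes up to 4 members with the smallest p. Yes1, the SRC-family kinases and a few homeobox genes are named whatever their result. Some genes that the rule names are not reported here, though counts include them. A gene outside the rule is said to have been chosen after its values were seen.

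The tests were tested on simulated data made from the libraries' own means and spread over all 12565 genes, each drawn independently. Genes changed by known amounts were taken only from those with a mean log2(FPKM + 1) above 1, so the shares recovered do not cover lower genes. Of genes changed by a log2 of 2, limma recovered 56.7% in AE9a+Meis2 against AE9a, 52.2% in AE+Meis2 against AE9a+Meis2 and 44.8% in AE+Meis2 against AE9a. Of those changed by a log2 of 4, it recovered 84.8%, 87.9% and 83.3%, but of those changed by a log2 of 1 only 5.97%, 16.4% and 2.99%. It also called 10, 7 and 5 unchanged genes. Other settings, fixed with the design, were other pseudocounts (0.1 and 0.01), no filter and a stricter one (a mean of at least 5 FPKM), quantile and median ratio scaling, only the libraries of both groups, robust moderation, no trend, array weights, the replicate number as a block, an added log2 limit of 1 and each library left out in turn. Chosen after seeing the data were fits without small RNA entries and genes listed at 0 across a group, without the 2 libraries with values in silent genes, without the 2 libraries with high Y-linked values, array weights with those entries left out, and the homeobox list without Meis2. With AE9a reduced to 1 library, the lone sample is assumed to vary like the others. Gene positions are from GENCODE M21 on the same mouse build, matched by symbol for 22694 of the 23997 genes (94.6%).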

Results

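Marrow from mice treated with 5-fluorouracil, which enriches stem and progenitor cells, was taken 4 days later and cultured with the cytokines IL3, IL6 and SCF. It was transduced with a leukemia fusion gene, with or without Meis2, and given 48 hours later to irradiated recipients. RNA was prepared from the marrow of recipients that had developed leukemia, and sequenced. AML1-ETO (AE) joins RUNX1, a master regulator of blood formation, to the corepressor RUNX1T1, and AML1-ETO9a (AE9a) is a shorter splice form of it. Meis2 is a homeobox transcription factor of the TALE class. Median latency was 171 days for AE+Meis2, 102 days for AE9a+Meis2 and 138 days for AE9a. The design asked how these leukemic marrows resemble each other and differ. Values per library below are in order of replicate number.

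The transduced genes were examined in every library first. Meis2 (chromosome 2, 115863064 to 116065839) stood at 621, 604 and 1277 FPKM in AE9a+Meis2, against 6.99 and 13.2 in AE9a, a log2 difference of 6.20 ± 0.72. In AE+Meis2 it stood at 13.1, 38.2 and 81.5 FPKM, 4.45 log2 below AE9a+Meis2 (-4.45 ± 0.65) and 1.75 ± 0.72 above AE9a. Over all genes none of these passed (limma with Benjamini-Hochberg, adjusted p = 0.082, 0.14 and 0.83). Adjusted over the homeobox list alone, Meis2 passed in AE9a+Meis2 against AE9a (limma, adjusted p = 0.00046) and in AE+Meis2 against AE9a+Meis2 (0.0019), and it did not in AE+Meis2 against AE9a (0.15). Runx1t1 (chromosome 4, 13743436 to 13893649), the mouse counterpart of the ETO part, reached 223 and 218 FPKM in AE+Meis2 replicates 2 and 3. The library labelled AE+Meis2 replicate 1 had 21.6 FPKM of Runx1t1, inside the range of 10.3 to 26.8 FPKM in the 5 libraries with AE9a. Meis2 in that library, 13.1 FPKM, lay below the 13.2 FPKM of AE9a replicate 2. Both transduced genes thus go against the label of this library, and every direction below that involves AE+Meis2 includes it. Runx1 (chromosome 16, 92601466 to 92826149), which lies in all 3 groups' fusions, was at 23.1 to 71.1 FPKM, with log2 differences between -0.80 and -0.20, none past the threshold. The species of the transduced sequences is not given in the sources used here, so FPKM counts whatever part aligned to the mouse genes.

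**Figure D1:**
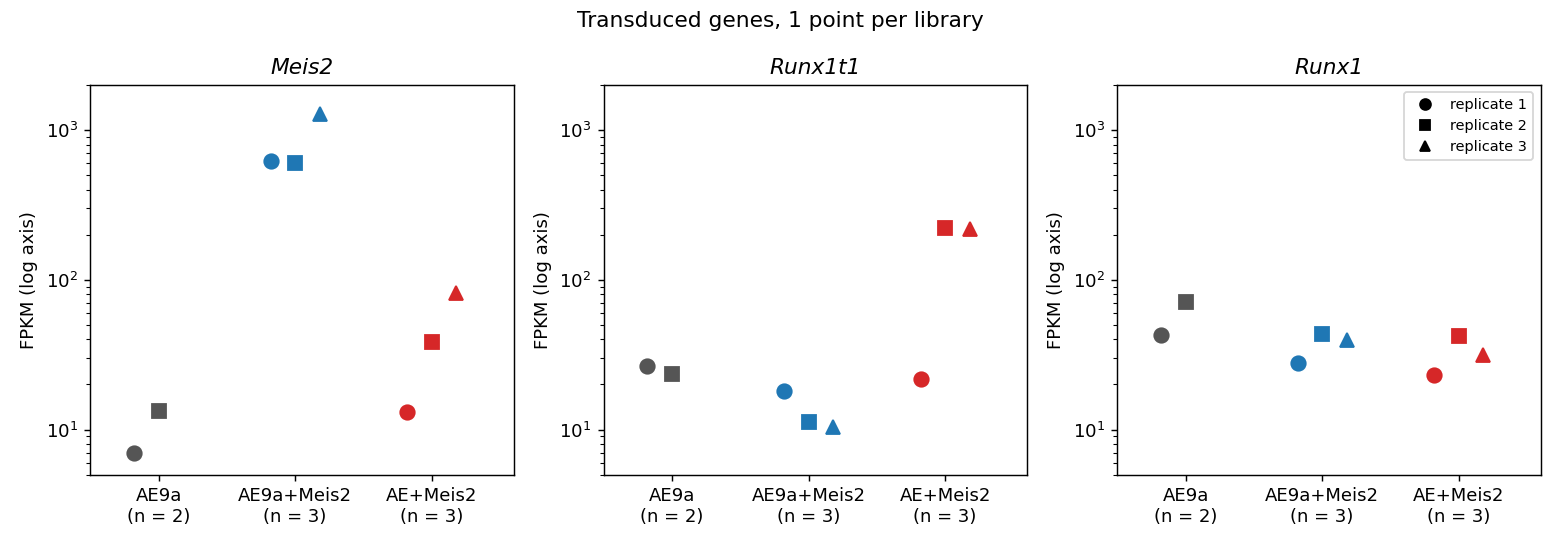
Meis2, Runx1t1 and Runx1 in FPKM on a log axis, 1 point per library, with the marker shape giving the replicate number. Meis2 was highest in AE9a+Meis2 (604 to 1277 FPKM), and Runx1t1 reached 223 and 218 FPKM in AE+Meis2 replicates 2 and 3 but not in the library labelled AE+Meis2 replicate 1 (21.6 FPKM).

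Related homeobox genes were low. Meis1, the TALE factor best known from myeloid leukemia, was at 3.67, 1.61 and 1.93 FPKM in AE+Meis2 and at 0.0228, 0.0449 and 0.491 FPKM in AE9a+Meis2 (log2 1.5 ± 0.31, limma adjusted p = 0.32 over all genes and 0.0085 adjusted over the list alone). Meis3 was lower than in AE9a in both other groups (log2 -1.34 ± 0.32 for AE9a+Meis2 and -1.61 ± 0.32 for AE+Meis2, limma adjusted p = 0.018 and 0.013 adjusted over the list alone). Hoxb4, a gene that expands blood stem cells, was lower in AE+Meis2 than in AE9a+Meis2 (log2 -1.45 ± 0.41, adjusted p = 0.031 by limma adjusted over the list alone). Pbx3 did not pass in any comparison (log2 differences of -0.48 to -0.23). Hoxa9 stayed at or below 0.698 FPKM in every library, and Hoxa7 and Hoxa10 were too low to be tested. The homeobox list as a whole did not pass camera (adjusted p = 0.76, 0.26 and 0.91 in the order AE9a+Meis2 against AE9a, AE+Meis2 against AE9a+Meis2, AE+Meis2 against AE9a), and its median (-0.16) and mean (0.47) differed in sign in the first. The list holds the transduced gene Meis2. By fry's test for change in either direction the adjusted p was 0.010, 0.0052 and 0.0073 with Meis2, and 0.13, 0.046 and 0.0072 without it, a setting chosen after seeing the data. The mean in the first comparison was -0.17 without Meis2. SRC-family kinases did not pass either (camera adjusted p = 0.82, 0.72 and 0.76); their median and mean differed in sign in both comparisons with AE9a (0.12 and -0.06, 0.10 and -0.06). Yes1, a member of that family, was between 0.0753 and 0.538 FPKM in all libraries, below the filter, and Fyn differed from AE9a by -0.93 ± 0.50 and -1.11 ± 0.50.

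The libraries differed in ways the groups do not explain. Relative depth, set against AE9a+Meis2 replicate 2 at 100%, could be estimated only roughly, the lowest and highest estimates of several libraries lying far apart. They were 18.2% to 36.5%, about 14.8% and 20.01% to 40.04% in AE+Meis2, 32.9% to 65.7% and 15.7% to 31.5% in AE9a+Meis2 replicates 1 and 3, and about 12.1% and 21.5% to 43.1% in AE9a. The Y-linked gene Eif2s3y was at 158 and 176 FPKM in AE+Meis2 replicates 1 and 2, at 7.06 FPKM in replicate 3 and at most 0.574 FPKM in the other 5 libraries. Xist, expressed from an inactive X, was at 1.93 and 5.79 FPKM in those first 2 libraries and at 82.4 to 206 FPKM in the others. Sex of the cells therefore differs between groups and within AE+Meis2. The sex-linked list was higher in AE+Meis2 than in AE9a+Meis2 (camera with Benjamini-Hochberg, adjusted p = 0.0048, and adjusted p = 0.69 with an estimated correlation) and than in AE9a (0.0093, and adjusted p = 0.86 with an estimated correlation). It did not pass without the library labelled AE+Meis2 replicate 1 (adjusted p = 0.27 and 0.44) or without replicate 2 (0.18 and 0.38), nor, against AE9a, without AE9a replicate 2 (0.054).

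Genes of families that marrow does not use, namely olfactory and vomeronasal receptors, keratin-associated proteins and beta-defensins, divided the libraries in another way. Of 1543 such genes, 84.1% in AE9a+Meis2 replicate 3 and 72.1% in AE9a replicate 1 were above 0, against 3.37% to 6.61% in the other 6 libraries. Their mean was 0.461 and 0.597 FPKM in the 2 libraries and at most 0.0461 FPKM elsewhere. These 2 libraries belong to different groups, and both enter the comparison of AE9a+Meis2 with AE9a. A further division followed the groups exactly. Eef1a1, the translation elongation factor that brings transfer RNA to the ribosome (chromosome 9, 78478449 to 78489151), was listed at 0 in all 3 AE9a+Meis2 libraries, at 6376, 8302 and 5756 FPKM in AE+Meis2 and at 6164 and 5898 FPKM in AE9a. Fibronectin Fn1 (chromosome 1, 71585520 to 71653200) was also listed at 0 in all 3 AE9a+Meis2 libraries, and was at 59.0, 80.8 and 57.1 FPKM in AE+Meis2 and at 99.8 and 223 FPKM in AE9a. S100a9, a subunit of calprotectin (chromosome 3, 90692632 to 90695721), was listed at 0 in all 3 AE+Meis2 libraries, and was at 466, 5731 and 22245 FPKM in AE9a+Meis2 and at 2806 and 10900 FPKM in AE9a. Its partner S100a8 was at 11060, 1149 and 131100 FPKM in AE+Meis2. Of 4255 genes with a median over 20 FPKM, 4 held any value of 0, these among them, and each was at 0 across exactly 1 group.

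**Figure D2:**
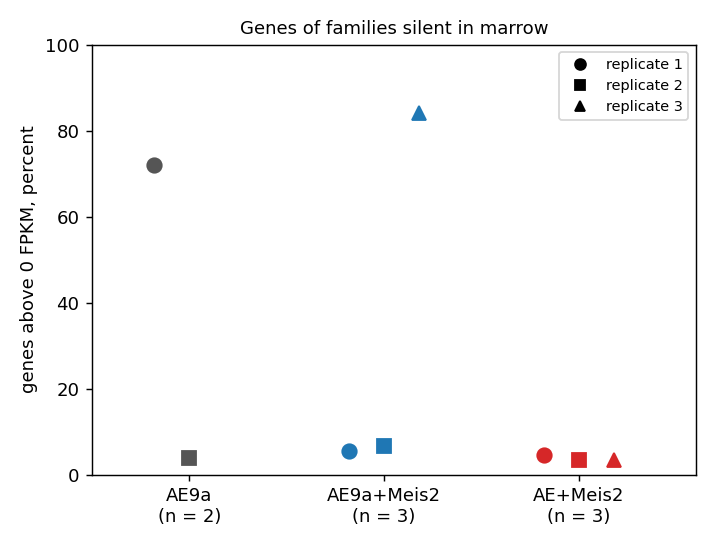
Percentage of 1543 genes of families silent in marrow with an FPKM above 0, 1 point per library, with the marker shape giving the replicate number. AE9a+Meis2 replicate 3 (84.1%) and AE9a replicate 1 (72.1%) lie far above the other 6 libraries (3.37% to 6.61%).

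The first comparison asked what differed when Meis2 accompanied the truncated fusion. Interferon response genes rose in AE9a+Meis2 (n = 3) over AE9a (n = 2): all 32 tested members were higher, with a median log2 difference of 1.28 (camera with Benjamini-Hochberg, adjusted p = 1.6e-28). The call was lost at adjusted p = 0.26 with an estimated correlation, and over 16 alternatives the adjusted p ranged from 9.4e-36 to 0.39. Adjusted over the list alone, 4 members passed limma. Ifitm3, a membrane protein that blocks virus entry (chromosome 7, 141009586 to 141010770), was at 353, 383 and 704 FPKM against 108 and 73.7 (log2 2.34 ± 0.33). Zbp1, a sensor of Z-form nucleic acid (chromosome 2, 173206612 to 173218923), differed by 2.53 ± 0.44. The RNA sensor Ifih1 differed by 1.29 ± 0.27, and Irf7, which amplifies interferon production, by 2.47 ± 0.63. Over all genes 0 members passed limma, and 17 were higher at an unadjusted p under 0.05.

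MHC class I and antigen processing rose as a list too, 14 of 15 being higher and none passing limma adjusted over the list alone. The median log2 was 0.50 (camera adjusted p = 7.7e-07, and adjusted p = 0.26 with an estimated correlation). The proteasome subunit Psmb10 differed by 0.68 ± 0.20 and the light chain B2m by 0.68 ± 0.29. Without AE9a replicate 2 the list did not pass (mean log2 0.11, adjusted p = 0.15), and without AE9a replicate 1 its mean rose from 0.46 to 0.80; the adjusted p ranged from 4.7e-11 to 0.39 over the alternatives. The list of stress and dissociation genes, a sign of how tissue and RNA were handled, rose in the same comparison, 17 of 19 being higher (median log2 1.61, camera adjusted p = 7.2e-09, and adjusted p = 0.34 with an estimated correlation). Atf3, an early stress-induced transcription factor, differed by 2.61 ± 0.47 and passed limma adjusted over the list alone. The immediate early genes Fos, Jun and Dusp1 differed by 3.61 ± 1.38, 2.94 ± 1.02 and 3.24 ± 1.29. Without the 2 libraries with values in silent genes, the mean of this list went from 1.42 to 0.90.

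The unfolded protein response list rose, 19 of 21 being higher (median log2 0.49, camera adjusted p = 3.4e-06, and adjusted p = 0.55 with an estimated correlation), with Atf4, its translational arm's main activator, at 0.51 ± 0.21. Atf3 belongs to this list as well as to the stress list, and 1 member of this list passed limma adjusted over the list alone. Replication-dependent histones rose as a list, 10 of 12 tested members being higher and none passing limma adjusted over the list alone (median log2 0.59, camera adjusted p = 5.5e-06, and adjusted p = 0.42 with an estimated correlation), with Hist1h2bc at 0.87 ± 0.24. Stroma and endothelium genes fell as a list, 8 of 13 being lower and none passing limma adjusted over the list alone. Their median log2 was -0.71 (camera adjusted p = 0.00083, and adjusted p = 0.26 with an estimated correlation). Among these, Fabp4, a fatty acid carrier of fat and endothelial cells, was at 25.7, 14 and 9.32 FPKM against 92.5 and 56.2 (log2 -2.19 ± 0.58), and the niche chemokine Cxcl12 differed by -1.16 ± 0.51. These 3 lists, with the interferon and stress lists, passed camera in each of the 8 fits that left out 1 library.

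Glycolysis and hypoxia genes were higher in 18 of 24 (median log2 0.31, camera adjusted p = 0.0082, and adjusted p = 0.34 with an estimated correlation), with Egln3, an oxygen-sensing hydroxylase, at 1.83 ± 0.70. That list's mean of 0.29 was 0.45 without AE9a replicate 1, and it did not pass without AE9a replicate 2 (mean log2 0.13, adjusted p = 0.58) or under quantile scaling (0.17, adjusted p = 0.14). Literature targets repressed by RUNX1-ETO were higher in 18 of 21 (median log2 0.49, camera adjusted p = 0.016, and adjusted p = 0.71 with an estimated correlation). Cebpa, the granulocyte lineage factor, was at 59.4, 32.5 and 18 FPKM against 13 and 9.50 (log2 1.48 ± 0.47). This list did not pass without AE9a replicate 1 (mean log2 0.29 in place of 0.51, adjusted p = 0.081), AE9a+Meis2 replicate 3 (0.071) or both libraries with values in silent genes (0.23). A further 3 lists lay at the threshold, each with camera adjusted p = 0.049, and adjusted p = 0.94 with an estimated correlation. G2 and mitosis genes (28 of 32 lower, median log2 -0.17) did not pass without AE+Meis2 replicate 1, AE9a+Meis2 replicate 1 or AE9a+Meis2 replicate 3 (adjusted p = 0.061, 0.31 and 0.69). MYC and nucleolar genes (24 of 27 lower, median -0.13) did not pass without AE9a+Meis2 replicate 1 or 3 (0.30 and 0.11), and were at 0.0502 without AE+Meis2 replicate 1. Their means of -0.17 and -0.16 were -0.40 and -0.27 without AE9a+Meis2 replicate 2 and -0.42 and -0.47 without AE9a replicate 1, and turned positive without AE9a replicate 2 (0.07 and 0.16). The mitosis mean was also positive without AE9a+Meis2 replicate 3 (0.0059). RAS-MAPK feedback and AP-1 genes (13 of 20 higher, median 0.28) did not pass without AE+Meis2 replicate 1, AE9a replicate 1 or AE9a+Meis2 replicate 3 (0.061, 0.26 and 0.56), and their mean of 0.91 was 0.59 without AE9a replicate 1. Nor did they pass without both libraries with values in silent genes (0.88). Their list shares Fos, Jun, Junb, Egr1, Ier2 and Dusp1 with the stress and dissociation list, so it is not a result separate from that list.

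Over the alternatives, the adjusted p ran from 8.8e-14 to 0.47 for stress, 6.2e-07 to 0.64 for the unfolded protein response, 4.8e-09 to 0.47 for histones and 0.00019 to 0.47 for stroma. It ran from 0.0002 to 0.59 for glycolysis, 0.0011 to 0.97 for RUNX1-ETO targets and RAS-MAPK, 8.0e-07 to 0.97 for mitosis and 1.7e-06 to 0.97 for MYC. In all, 11 of 39 lists passed camera, and none passed with an estimated correlation or by fry's test for 1 direction, where 0 of 39 passed.

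Monocyte and macrophage genes did not pass as a list (camera adjusted p = 0.21). Klf4 (log2 2.01 ± 0.36) and Irf8 (1.79 ± 0.35), both transcription factors of monocyte development, were higher in AE9a+Meis2, and Spic (-2.61 ± 0.55), a factor of iron-recycling macrophages, was lower, by limma adjusted over the list alone. Single genes gave 6 calls over all 12565 tested (3 higher and 3 lower, limma with Benjamini-Hochberg). Among the lower were Eef1a1 (limma adjusted p = 3.9e-07) and Fn1 (0.00059), both listed at 0 in AE9a+Meis2. The 3 higher were small RNAs, chosen here after their values were seen: Mir7063 at 849, 154 and 802 FPKM, Snora75 at 148, 78.7 and 41.4 FPKM and Snora31 at 192, 76.9 and 180 FPKM, each listed at 0 in both AE9a libraries. With small RNAs and genes listed at 0 across a group left out, limma called 0 genes at the threshold and 388 at an unadjusted p under 0.05, where chance alone gives 619.75 of the 12395 tested. With only the libraries of both groups and those entries kept, 957 of 12171 genes had such a p, against 385 of 12565 over all 8 libraries. The count thus depends on whether the AE+Meis2 libraries enter the spread. Among genes that did not pass, Tcea3, a transcription elongation factor, was at 6.00, 13.4 and 9.09 FPKM against 0.121 and 0.579 (log2 2.92 ± 0.35, limma adjusted p = 0.088). Galnt9, a glycosyltransferase, differed by 2.04 ± 0.29. Smpx, a small muscle protein, was at 1.5, 0.0178 and 1.51 FPKM against 29.5 and 17.7 (log2 -3.69 ± 0.45, limma adjusted p = 0.088). Without AE9a replicate 1 the count of genes fell from 6 to 2.

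The second comparison set the full-length fusion against the truncated one, both with Meis2. Interferon response genes were higher in AE+Meis2 (n = 3) than in AE9a+Meis2 (n = 3) in 29 of 32 tested members, with a median log2 difference of 0.69 (camera with Benjamini-Hochberg, adjusted p = 6.0e-06, and adjusted p = 0.83 with an estimated correlation). The RNA sensors Ddx58 (chromosome 4, 40203773 to 40239828) and Ifih1 differed by 1.63 ± 0.32 and 0.99 ± 0.24, while Ifitm3 went the other way (-1.22 ± 0.30). These 3 passed limma adjusted over the list alone. Without the library labelled AE+Meis2 replicate 1 the list's mean went from 0.74 to 0.44 (adjusted p = 0.014). Without both libraries with high Y-linked values it did not pass (0.11), and over 16 alternatives the adjusted p ranged from 8.4e-14 to 0.83.

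Klf4 and Irf8, transcription factors of monocyte development, were lower in AE+Meis2 by limma adjusted over the list alone. Klf4 (chromosome 4, 55527143 to 55532466) was at 3.91, 4.96 and 9.32 FPKM against 38.4, 30.0 and 45.2 (log2 -2.51 ± 0.32), and Irf8 (chromosome 8, 120736358 to 120756694) at 8.14, 10.2 and 16 FPKM against 94.6, 59.2 and 50.2 (-2.47 ± 0.32). Neither passed over all genes (limma adjusted p = 0.080 for both). The monocyte list as a whole did not pass camera (adjusted p = 0.41) but passed fry's test for change in either direction (0.021), with the mannose receptor Mrc1 higher (1.88 ± 0.50) and the chemokine receptor Ccr2 lower (-1.60 ± 0.43). Spic, the macrophage factor, was at 6.37, 1.66 and 1.37 FPKM against 0.505, 0.519 and 0.917 and did not pass. Cebpa differed by -1.78 ± 0.42. Of 24 stem and progenitor genes, 21 were higher (median log2 0.43, camera adjusted p = 0.042, and adjusted p = 0.83 with an estimated correlation). Angpt1, a ligand of the receptor Tek, was higher (2.37 ± 0.61), and the cytokine receptor Flt3 was at 7.57, 4.93 and 6.49 FPKM against 53.3, 28.1 and 13.1 (-1.96 ± 0.47). Both passed limma adjusted over the list alone. The stem list did not pass without the library labelled AE+Meis2 replicate 1 (0.35), AE+Meis2 replicate 2 (0.051) or AE9a+Meis2 replicate 1 (0.086), nor without both libraries with high Y-linked values (0.62). Megakaryocyte and platelet genes were higher in 15 of 18 (median log2 0.60, camera adjusted p = 0.0076, and adjusted p = 0.83 with an estimated correlation). The platelet chemokine Pf4 differed by 3.41 ± 0.84, at 38.1, 82.4 and 5.90 FPKM against 2.56, 2.06 and 0.715. This list did not pass without AE+Meis2 replicate 2 (mean log2 0.25, adjusted p = 0.20), had a mean of 1.18 without AE+Meis2 replicate 3, and turned negative without both libraries with high Y-linked values (-0.45).

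Stroma and endothelium genes rose as a list in AE+Meis2, all 13 being higher and none passing limma adjusted over the list alone. Their median log2 was 1.01 (camera adjusted p = 0.0029, and adjusted p = 0.69 with an estimated correlation). Among them were the matrix protein Sparc (1.25 ± 0.47) and the adhesion molecule Vcam1 (1.65 ± 0.64). Replication-dependent histones fell as a list, all 12 being lower and none passing limma adjusted over the list alone (median log2 -0.50, camera adjusted p = 0.00057, and adjusted p = 0.83 with an estimated correlation), with Hist1h1a at -1.06 ± 0.29. Ribosomal protein genes were higher in 27 of 30 (median log2 0.23, camera adjusted p = 0.00057, and adjusted p = 0.84 with an estimated correlation), with Rps3 at 0.48 ± 0.17, but under quantile scaling the list passed in the opposite direction (mean log2 -0.21, adjusted p = 0.015). None of these 3 passed without both libraries with high Y-linked values (adjusted p = 0.26, 0.22 and 0.69), and each passed in all 8 fits that left out 1 library. Glycolysis and hypoxia genes were lower in 18 of 24 (median log2 -0.38, camera adjusted p = 0.0084, and adjusted p = 0.69 with an estimated correlation). The enolase Eno1 differed by -0.79 ± 0.22 and the phosphofructokinase Pfkp by -0.60 ± 0.18, and the list did not pass without AE+Meis2 replicate 3 (0.091). Literature targets repressed by RUNX1-ETO (13 of 21 lower, median log2 -0.18) and MYC and nucleolar genes (21 of 27 higher, median 0.27) lay at camera adjusted p = 0.047 for both, with adjusted p = 0.83 and 0.89 with an estimated correlation. The first did not pass without AE+Meis2 replicate 2 (mean log2 0.23, adjusted p = 0.76), AE9a+Meis2 replicate 3 (0.17), AE9a replicate 1 (0.068) or AE9a replicate 2 (0.056), and its mean was -0.63 without AE+Meis2 replicate 3. The second did not pass without the library labelled AE+Meis2 replicate 1 (0.65), AE+Meis2 replicate 2 (0.49), AE9a+Meis2 replicate 1 (0.25) or AE9a+Meis2 replicate 3 (0.11), and its mean of 0.21 was 0.44 without AE+Meis2 replicate 3 and 0.32 without AE9a+Meis2 replicate 2. Neither passed without both libraries with values in silent genes (0.19 and 0.082) or without both with high Y-linked values (0.96 and 0.061), where both means turned (0.48 and -0.24). Over the alternatives, the adjusted p ran from 9.3e-06 to 0.84 for ribosomal proteins, 4.3e-06 to 0.83 for histones, 0.00026 to 0.69 for stroma, 8.4e-06 to 0.83 for megakaryocytes and 0.0043 to 0.83 for stem cells. It ran from 0.0028 to 0.69 for glycolysis, 0.0053 to 0.96 for RUNX1-ETO targets and 1.4e-05 to 0.94 for MYC. In all, 10 of 39 lists passed camera, and 0 with an estimated correlation.

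Single genes gave 5 calls over all genes tested, 4 higher and 1 lower in AE+Meis2 (limma with Benjamini-Hochberg). Among them, Eef1a1 (limma adjusted p = 1.6e-07) and Fn1 (0.00065) were listed at 0 in AE9a+Meis2, Mir7063 was listed at 0 in AE+Meis2, and Mir6386 was at 114, 279 and 110 FPKM in AE+Meis2 and listed at 0 in the other 5 libraries. The last 2 were chosen after their values were seen. With small RNAs and genes listed at 0 across a group left out, limma called 0 genes and 885 at an unadjusted p under 0.05, where chance alone gives 619.75 of the 12395 tested. Of genes that did not pass, the orphan receptor Gpr141 (chromosome 13, 19749682 to 19824257) was at 3.91, 7.40 and 7.04 FPKM against 57.7, 32.6 and 37.5 (log2 -2.61 ± 0.30, limma adjusted p = 0.065). Tcea3 (-2.84 ± 0.32), the collagen-binding integrin Itga1 (-1.97 ± 0.25) and Arhgef37 (-2.45 ± 0.31) were also lower, and the phosphatase Dusp2 was higher (1.45 ± 0.26). The count of genes was 8 without the library labelled AE+Meis2 replicate 1, 8 without replicate 2, 23 without replicate 3 and 9 without AE9a+Meis2 replicate 1.

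The third comparison, AE+Meis2 against AE9a, changed the fusion form and Meis2 together. Interferon response genes rose: all 32 tested members were higher in AE+Meis2 (n = 3) than in AE9a (n = 2), with a median log2 difference of 1.99 (camera with Benjamini-Hochberg, adjusted p = 1.3e-34, and adjusted p = 0.27 with an estimated correlation). Adjusted over the list alone 27 of them passed limma. The RNA sensor Ifih1 (chromosome 2, 62595798 to 62646255) was at 21.2, 26.8 and 16.6 FPKM against 3.78 and 3.38 (log2 2.27 ± 0.27), and Ddx58 at 36.4, 39.3 and 32.9 FPKM against 6.79 and 4.87 (2.46 ± 0.35). Ifit1, which binds viral RNA, differed by 3.77 ± 0.64. Over 16 alternatives the adjusted p ranged from 6.7e-51 to 0.27. Over all genes 0 members passed limma and 28 were higher at an unadjusted p under 0.05. Fry, which tests each list by itself, gave an adjusted p of 0.10 for a shift in 1 direction and 0.014 for change in either direction.

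Genes of MHC class I and antigen processing rose too, 14 of 15 being higher (median log2 0.75, camera adjusted p = 3.7e-08, and adjusted p = 0.27 with an estimated correlation). B2m was at 2545, 2700.3 and 2161 FPKM against 1203 and 859.6 (1.27 ± 0.29) and passed limma adjusted over the list alone. Without AE9a replicate 2 the list's mean went from 0.71 to 0.37 (adjusted p = 0.0099), and fry's test for change in either direction gave an adjusted p of 0.012. Stress and dissociation genes also rose as a list, 18 of 19 being higher and none passing limma adjusted over the list alone. Their median log2 was 0.80 (camera adjusted p = 4.3e-05, and adjusted p = 0.89 with an estimated correlation), with Egr1 at 2.26 ± 0.87. The libraries did not follow the interferon order: the stress score of AE+Meis2 replicate 2 (4.91) lay below that of AE9a replicate 2 (5.44). Their mean of 0.99 was 1.60 without AE+Meis2 replicate 2, 0.61 without replicate 3 and 0.56 without AE9a replicate 1. These 3 lists passed camera in each of the 8 fits that left out 1 library. The unfolded protein response list rose, 18 of 21 being higher and none passing limma adjusted over the list alone (median log2 0.56, camera adjusted p = 0.00072, and adjusted p = 0.99 with an estimated correlation), with the chaperone Dnajb9 at 1.31 ± 0.43, but not without AE+Meis2 replicate 3 (0.052). Ribosomal protein genes were higher in 26 of 30 (median log2 0.23, camera adjusted p = 0.0012, and adjusted p = 0.99 with an estimated correlation). Under quantile scaling the list passed in the opposite direction (mean log2 -0.21, adjusted p = 0.035), and it did not pass without AE+Meis2 replicate 2 (0.084) or AE9a replicate 2 (0.054), nor without both libraries with high Y-linked values (mean log2 0.09, adjusted p = 0.88).

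Primary granule genes, a list meant to mark promyelocytes, were higher in all 15 (median log2 1.25, camera adjusted p = 0.011, and adjusted p = 0.99 with an estimated correlation). None passed limma adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. Among those named by the rule were Calr at 0.95 ± 0.38, also a member of the unfolded protein response list, and Plac8 at 1.49 ± 0.81. The list rested on single libraries: it did not pass without the library labelled AE+Meis2 replicate 1 (0.14), AE+Meis2 replicate 3 (mean log2 0.26, adjusted p = 0.60) or AE9a replicate 1 (mean log2 0.49, adjusted p = 0.26), and its mean of 1.13 was 2.10 without AE+Meis2 replicate 2 and 1.76 without AE9a replicate 2. NF-kB and inflammatory genes were higher in 16 of 22 (median log2 0.45, camera adjusted p = 0.035, and adjusted p = 0.99 with an estimated correlation). The chemokine Cxcl2 was at 16.5, 3.74 and 385 FPKM against 0.429 and 0.241. The NF-kB list did not pass in 5 of the 8 fits that left out 1 library: without the library labelled AE+Meis2 replicate 1 (0.21), AE+Meis2 replicate 3 (0.052), AE9a+Meis2 replicate 3 (0.051), AE9a replicate 1 (0.14) or AE9a replicate 2 (0.054). Without both libraries with values in silent genes, neither primary granule (0.25) nor NF-kB genes (0.18) passed. Over the alternatives, the adjusted p ran from 1.6e-14 to 0.27 for MHC class I, 3.9e-10 to 0.89 for stress, 1.2e-06 to 0.99 for the unfolded protein response, 2.0e-05 to 0.99 for ribosomal proteins, 8.6e-08 to 0.99 for primary granules and 0.0011 to 0.99 for NF-kB. In all, 8 of 39 lists passed camera, and 0 with an estimated correlation.

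Single genes gave 4 calls, 3 higher and 1 lower (limma with Benjamini-Hochberg). Smpx (chromosome X, 157698910 to 157752591) was at 0.098, 0 and 0 FPKM in AE+Meis2 against 29.5 and 17.7 in AE9a (adjusted p = 0.049). It passed in 7 of 24 alternatives, with adjusted p from 0.018 to 0.47, and in 1 of the 8 fits that left out 1 library, the one without AE9a+Meis2 replicate 2 (0.022). The others, chosen after their values were seen, were Mir6386, Snora31 (206, 121 and 678 FPKM) and Snora75 (35.6, 83.0 and 66.1 FPKM), all listed at 0 in AE9a. With small RNAs and genes listed at 0 across a group left out, limma called 0 genes and 754 at an unadjusted p under 0.05 (619.75 by chance alone). With only the libraries of both groups and those entries kept, 473 of 11919 genes had such a p, against 752 of 12565 over all 8 libraries. This count too depends on which libraries enter the spread. Parp14, an interferon-inducible ADP-ribosyltransferase (chromosome 16, 35832874 to 35871544), was at 33.0, 33.5 and 34.4 FPKM against 11.9 and 11.0 (log2 1.48 ± 0.18, limma adjusted p = 0.11). The antiviral factor Trim30a differed by 2.27 ± 0.28 and the class I gene H2-T24 by 2.6 ± 0.37, while Hoxc4 was lower (-3.22 ± 0.43). The count of genes was 1 without the library labelled AE+Meis2 replicate 1, 10 without AE+Meis2 replicate 3, 1 without AE9a replicate 1 and 2 without AE9a+Meis2 replicate 2.

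**Figure D3:**
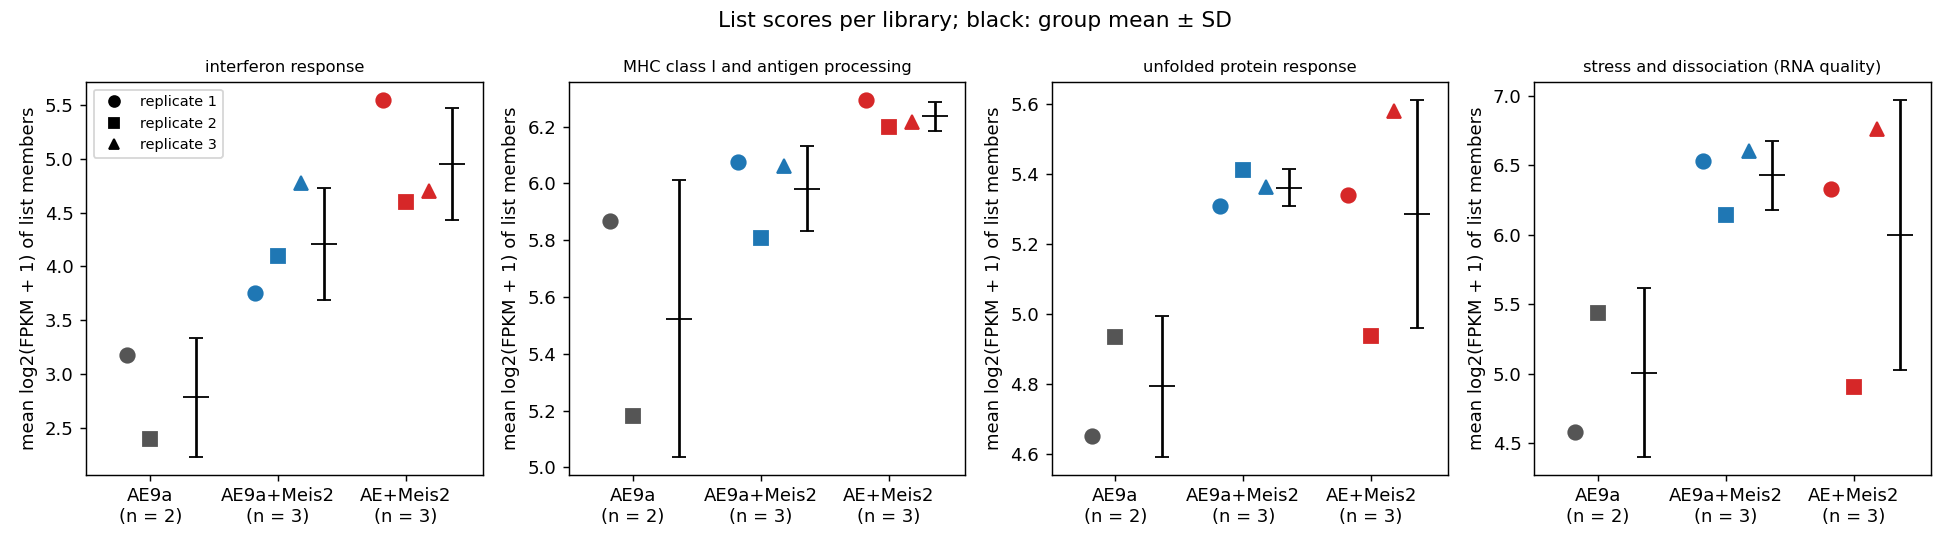
Mean log2(FPKM + 1) over the members of 4 gene lists, 1 point per library, with black bars for the group mean and SD. Interferon scores were 2.78 ± 0.555 in AE9a (n = 2), 4.21 ± 0.518 in AE9a+Meis2 (n = 3) and 4.95 ± 0.518 in AE+Meis2 (n = 3).

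**Figure D4:**
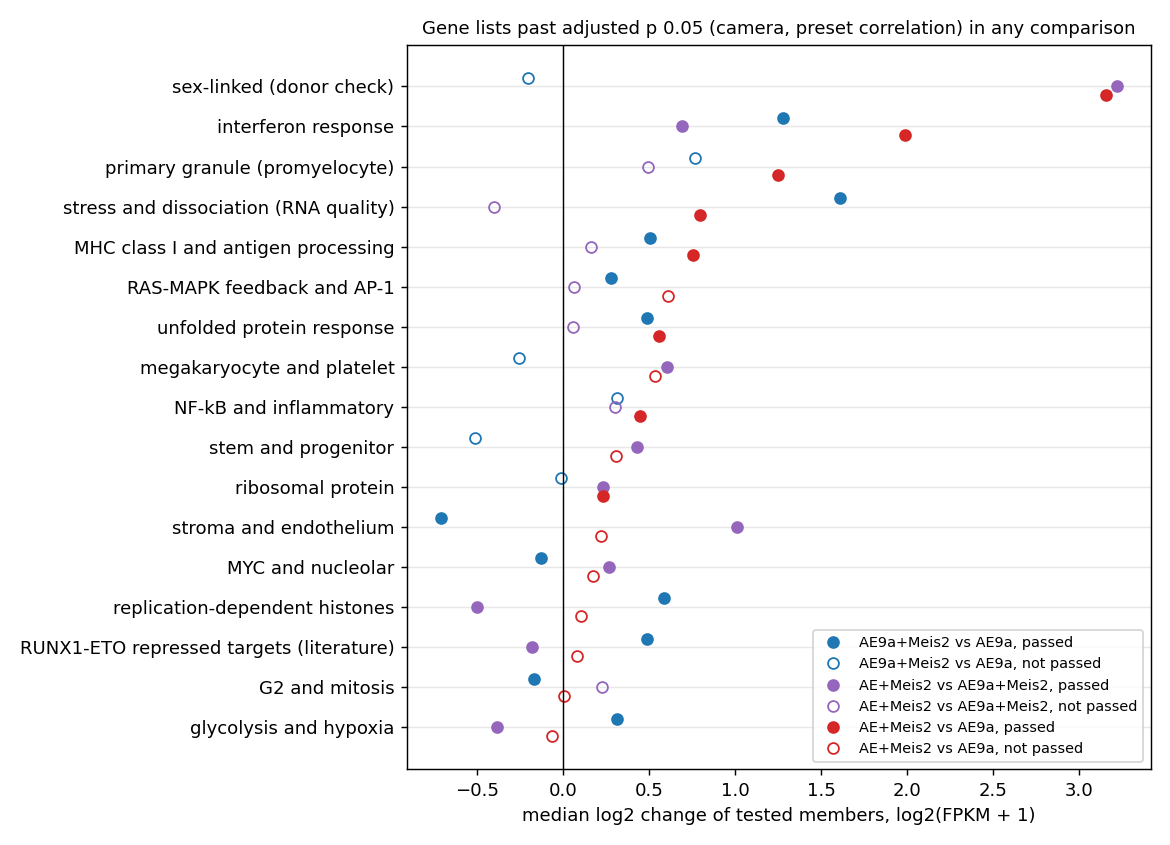
Median log2 difference of each list that passed camera at the preset correlation in any comparison, with filled points for passed and open points for not passed. Interferon response medians were 1.28, 0.69 and 1.99, and ribosomal protein means turned negative under quantile scaling (-0.21 in both comparisons where that list passed).

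The comparisons share libraries, so their fold changes are related by construction. Both comparisons with AE9a called 2 genes in common, Snora31 and Snora75 in the same direction, where independent lists would share 0.000955. Across genes, which are not independent replicates, their log2 differences had a correlation of 0.50, against 0.60 (0.54 to 0.65 over 100 draws) simulated with no effect and the same shared libraries. The covariance was 0.221 against 0.224 simulated. AE9a holds 2 libraries, too few for each comparison to have at least 2 of its own, so part of the shared calls may come from those libraries. The comparisons that share AE9a+Meis2 called 4 genes in common, Eef1a1, Fn1 and Mir7063 among them, all in opposite directions, with a correlation of -0.39 against -0.45 simulated and a covariance of -0.161 against -0.148. Those that share AE+Meis2 called Mir6386 in common, with a correlation of 0.61 against 0.44 and a covariance of 0.293 against 0.147 (0.0966 to 0.176 over the draws). The simulation gave all libraries the same spread per gene. Correlations among the AE+Meis2 libraries were 0.752 to 0.859, against 0.859 to 0.921 among AE9a+Meis2. Values outside the simulated range therefore cannot be told apart from unequal spread.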

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

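Fits without small RNA entries and genes listed at 0 across a group, without the 2 libraries with values in silent genes, without the 2 with high Y-linked values, array weights with entries left out and the homeobox list without Meis2 were chosen after seeing the data. Counts below are in the order AE9a+Meis2 against AE9a, AE+Meis2 against AE9a+Meis2, AE+Meis2 against AE9a. Where a value differs, the cause was not tested.

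Genes past the threshold (6, 5 and 4 by limma) were 13, 1583 and 84 with array weights, which gave the library labelled AE+Meis2 replicate 1 a weight of 5.77 and AE9a+Meis2 replicate 2 a weight of 8.33. With array weights and those entries left out the last 2 were 1713 and 88. Without small RNA entries and group-wide zeros they were 0, 0 and 0. The first was 3 without the 2 libraries with values in silent genes. Without the 2 libraries with high Y-linked values, which leaves 1 AE+Meis2 library assumed to vary like the others, the last 2 were 13 and 228. The last was 1 with no filter and 2 with only the libraries of both groups. Leaving out 1 library gave 2 to 9, 6 to 23 and 1 to 10. Replicate numbers showed no clear pairing of the libraries, though pairing cannot be excluded. Correlations of same-number deviations ran from -0.025 to 0.133 over 7 pairs, 1 of them over 0.1, against -0.101 to 0.083 in other pairs. With the number as a replicate block the first and last counts were 2 and 0.

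Lists past the threshold (11, 10 and 8 by camera) were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 by fry's test for 1 direction (1, 2 and 3 by its test for either direction, and 0, 2 and 3 with Meis2 left out of the homeobox list), 19 for the first without the 2 libraries with values in silent genes, 13 for the last under quantile scaling, and 18, 5 and 15 without the 2 with high Y-linked values. Leaving out 1 library gave 9 to 17, 8 to 16 and 7 to 10; the first was 17 without AE+Meis2 replicate 3 and the second 16 without AE9a+Meis2 replicate 2. Mean log2 differences turned for ribosomal proteins under quantile scaling (-0.214 and -0.210 in AE+Meis2 against AE9a+Meis2 and AE9a). Without the 2 libraries with high Y-linked values, the means of megakaryocyte genes (-0.446), MYC genes (-0.244) and RUNX1-ETO repressed targets (0.475) turned in AE+Meis2 against AE9a+Meis2, and camera's direction turned for stem genes though their mean stayed at 0.247. Without AE9a replicate 2, mitosis (0.0734) and MYC (0.158) genes turned in AE9a+Meis2 against AE9a, with lows of -0.417 and -0.472 without AE9a replicate 1. Eef1a1 and Fn1 passed in all 22 alternatives that kept them. This follows from their being listed at 0 in every AE9a+Meis2 library, which can be a failed estimate, and is no sign of a firm result.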

Other observations

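All tests in this part were chosen only after the results were seen.

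The 3 libraries of AE+Meis2 held different levels of mature cell genes. Neutrophil scores without S100a9, as mean log2(FPKM + 1), were 7.345, 4.96 and 10.6 in AE+Meis2, against 5.39 to 8.42 in the other 5 libraries. S100a8, the other subunit of calprotectin, was at 11060, 1149 and 131100 FPKM, which was 1.42%, 0.133% and 12% of the summed FPKM. These genes were chosen after their values were seen. The antimicrobial peptide Camp was at 747.8, 79.6 and 16410 FPKM. Mast cell scores were 6.54, 3.14 and 5.15 and erythroid scores 6.37, 6.05 and 3.41 in the same libraries. Ms4a2, the beta chain of the IgE receptor, was at 226, 4.65 and 58.3 FPKM, against 106 to 558 FPKM in the other 5 libraries. Correlations between libraries of the same group ran from 0.752 to 0.921 (median 0.859 over 7 pairs) and between groups from 0.787 to 0.908 (median 0.865 over 21 pairs).

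Genes of families silent in marrow were above 0 in AE9a+Meis2 replicate 3 and AE9a replicate 1. Deeper sequencing would leave the mean FPKM of these genes alike, and the lower of the 2 libraries stood 10.01-fold above the highest of the other 6. RNA of 1 other tissue would raise few families, and the family with the lowest share still had 27.91% of its genes above 0 in the 2, against at most 9.302% elsewhere. Genomic DNA of the same cells is a candidate source: quiet Y genes, absent from female cells, were above 0 in at most 5.882% of 34 genes, against at least 76.6% of quiet autosomal genes and 60.72% of quiet X genes. Against this, Uba1y, 1 of 5 Y genes looked at singly, was at 1.03 and 2.20 FPKM in the 2 libraries and at most 0.366 FPKM elsewhere, while Sry, Usp9y, Zfy1 and Zfy2 were at most 0.0493 FPKM; many Y genes also have several copies, so this source stays open, and no biological explanation was tested.

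Interferon genes were higher in both Meis2 groups than in AE9a, with scores differing by 1.80, the largest of the 28 splits of the 8 libraries (exact permutation p = 0.0357, the smallest possible, Benjamini-Hochberg 0.557 over the lists). In the same split unfolded protein response scores differed by 0.53, also the largest, and stress and dissociation scores by 1.20 (2 of the 28 splits as large). Whether handling of the tissue contributes to the interferon difference was not tested. Without the libraries with values in silent genes the lower mean log2 difference was still 1.536, so those libraries alone do not make it. AE9a then held only replicate 2, the library with the lowest score (2.39), so the size of that difference cannot be judged. The largest difference among monocyte, dendritic, B, T and NK scores was 0.2853 (highest with 2 standard errors, 1.3162). For dendritic, B, T and NK cells this argues against a rise as large as that of the interferon genes, and a smaller rise is not excluded. For monocytes the mean cannot decide, since the list's members moved both ways. In AE9a+Meis2 against AE9a, 7 of its members were higher and 3 lower at an unadjusted limma p under 0.05. A response in proportion to Meis2 RNA would put AE+Meis2 below AE9a+Meis2 (by -1.024), and it lay 0.742 ± 0.429 above, with the highest score, 5.55, in the library labelled AE+Meis2 replicate 1, whose Meis2 (13.1 FPKM) was no higher than in AE9a replicate 2 (13.2 FPKM, score 2.39). These 2 groups also differ in fusion form and in sex of the cells, so the comparison cannot separate the level of Meis2 from those. A larger share of neutrophils cannot be told apart from the interferon difference, as their score without S100a9 differed by 0.4509 with a standard error of 1.712. Still, AE+Meis2 replicate 2 and AE9a+Meis2 replicate 1 lay above both AE9a libraries in interferon score and below both in neutrophil score. A threshold response to Meis2, against which that labelled library speaks, and inflammation of the host may contribute and were not tested.

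The library labelled AE+Meis2 replicate 1 had neither Meis2 nor Runx1t1 raised. A swap with a library of another group would leave a partner with high Runx1t1, and the highest outside AE+Meis2 was 26.75 FPKM, against 218 in AE+Meis2 replicate 3. Eif2s3y at 158 FPKM, Xist at 1.93 FPKM and Meis1 at 3.67 FPKM lay on the side of AE+Meis2 replicate 2 (176, 5.79 and 1.61 FPKM). The labelled library correlated at 0.843 and 0.859 with AE+Meis2 replicates 2 and 3, and at 0.873 to 0.901 with every library of the other groups. Yet replicates 2 and 3 each had their highest correlation with the labelled library. With all remaining libraries replicate 2 correlated at 0.752 to 0.839 and replicate 3 at 0.752 to 0.858. These correlations therefore cannot decide whether the label is right. A single wrong label, or few transduced cells in this marrow, may account for the low Meis2 and Runx1t1 and were not tested.

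In AE+Meis2 against AE9a+Meis2, limma called 5 genes, and 1 of the 10 splits of the 6 libraries gave as many, with 3 as the highest of the others. Of the 5, 3 were genes listed at 0 across a group and 2 were small RNAs. Zeros across a group follow the real groups, which favours the real split from the start, so these counts cannot weigh chance. With small RNAs and genes listed at 0 across a group left out, limma called 0 genes in each of the 10 splits; over all genes, 898 had an unadjusted p under 0.05 in the real split and 935 in the highest other. The 10 splits are too few for a share under 0.05.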
